A study of Mus musculus with 32 samples.

How the data were processed

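Poly(A)-enriched RNA of 32 libraries of primary white adipocytes from subcutaneous adipose tissue of mice was sequenced, with 4 libraries in each of 8 groups. The groups combine 4 siRNA treatments (a scrambled sequence, siNfe2l1, siAtf3, or both target siRNAs) with control treatment or 400 µM cholesterol on methyl-β-cyclodextrin for 6 h. Per the submitters' processing notes, reads were trimmed with fastp, aligned to GRCm39 with HISAT2 2.0.5 and assigned to genes with featureCounts 1.5.0-p3. The deposited table holds raw read counts per gene for 56748 genes, without any scaling by the authors. Whether the libraries were stranded and how reads with several alignments were treated is not stated. Near-identical genes (Hspa1a and Hspa1b, the Mup cluster, Gm4841 and Tgtp2) are therefore named with their values but were not separated further. In the column names an added C was read as cholesterol, and the labels give no other key to it. The labels call the 4 libraries of a group biological replicates, and each p-value rests on a spread between replicates that was estimated over all 8 groups together.

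Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 by group (minimum count 10, minimum total 15), which left 16984 genes. Library sizes were scaled by TMM factors, which lay between 0.886 and 1.09. Group means of 8 groups were fitted in 1 robust quasi-likelihood model with 24 residual degrees of freedom, and contrasts were tested with glmQLFTest. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at a false discovery rate of 0.05. Levels are the CPM values of edgeR (counts relative to library size) on TMM-scaled library sizes, given as mean ± SD of 4 libraries, and log2 fold changes are given ± standard error (SE). The 17 contrasts are 12 comparisons of 2 groups and 5 interactions (differences between 2 such comparisons). With total counts of 23457384 to 33828418 per library, genes well below 1 CPM rest on few counts.

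Comparisons, tests, gene lists and the rule for the genes named were fixed before the data were examined. Named were Nfe2l1 and Atf3 in every comparison, and the 5 highest and 5 lowest log2 fold changes among called protein-coding genes with an average log2 CPM of at least 2 and no overlap between the groups (for interactions, without the condition on overlap). Genes called highest or lowest are so among these, apart from the silenced genes. Up to 4 called members per list with the smallest adjusted p were added, as were 11 genes watched in all comparisons, among them Abca1, Psmb5, Ddit3, Hspa5, Ccl2, Il6, Hmox1, Adipoq and Mt1. Not all genes so named are printed, and results of some are not reported here.

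The 22 gene lists cover cholesterol synthesis and SREBP2 targets, LXR targets and cholesterol efflux, fatty acid synthesis, proteasome subunits, the integrated stress response, endoplasmic reticulum chaperones, heat shock, cytokines with NF-kB targets, the interferon response, antioxidant NFE2L2 targets and metallothioneins. They also cover immediate early genes, p53 targets, lysosome and autophagy, adipocyte identity, thermogenic genes, fibroblast, macrophage, endothelial and smooth muscle markers, proliferation and mitochondrially encoded mRNAs. Each list was tested against all other genes with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison (374 tests in all). Of 198 list calls, 66 held with a correlation estimated from the data, and an adjusted p under that setting is given where a call was lost. Counts of list members are given over all genes tested and, where it differs, also adjusted over the list alone.

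The pipeline was tested on simulated data built from the siNfe2l1 and scramble control libraries. With 50 changed genes per size, it called 28 at 1.25-fold (56%), 90% at 1.5-fold, 98% at 2-fold and all at 4-fold. The 33 proteasome genes were lowered 1.25-fold as a list, of which 31 were called, and 10 of the 213 calls were false. Libraries of a group differed by more than counting error in each of 48 pairs (chi-square per degree of freedom 2.75 to 44.8), so none was a copy of another. The fit assumes that the groups vary alike. The highest value was 35.3 with scramble and 44.8 with siNfe2l1 in cholesterol, but 14.55 among control libraries. Gene p-values for comparisons of those 2 cholesterol groups may therefore be too small.

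Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom, fits on only the groups compared, the replicate number as a block, and leaving out each library in turn. Added after the data had been seen were scaling by library totals alone, leaving out the 8 libraries numbered 1, and leaving out scramble cholesterol library 1 with siNfe2l1 control library 4. A search for 7-base words in 3′ UTRs was also added then. It covered 10837 of 10895 protein-coding genes with an average log2 CPM of at least 2, with sequences of the GENCODE M21 transcripts joined by gene identifier and read with Biostrings 2.70.1. For 15623 words found in at least 100 genes, the log2 fold changes, limited to 2 in size, were regressed on presence of the word with 3′ UTR length, GC and A content and expression held constant, and z beyond -4.66 passed the Bonferroni limit. Words of a siRNA were chosen in its comparison with scramble in control medium. They passed there, occurred in the mRNA of the silenced gene and shared no 5-base stretch with a stronger word chosen. The siRNA sequences themselves were not used here. Protein, lipid and imaging data were not analysed here.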

Results

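Gene expression was measured by poly(A) RNA sequencing in mouse primary white adipocytes, fat-storing cells prepared from subcutaneous adipose tissue. Cells received a scrambled siRNA, siNfe2l1, siAtf3 or both target siRNAs (double silencing). They were then given control treatment, below called control medium, or loaded for 6 h with 400 µM cholesterol on methyl-β-cyclodextrin. This carrier is a ring of sugars that delivers sterols to membranes. The sample titles do not say whether the control treatment held the carrier, and an effect of the carrier was not tested. Each of the 8 groups held 4 libraries. Total counts ran from 23457384 to 33828418 per library, and all but 1 of the 32 libraries held at most 28391112. The study asked how Nfe2l1, a transcription factor that raises proteasome genes, and Atf3, a stress-induced transcription factor, bear on the response of adipocytes to cholesterol.

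The first principal component of the 1000 most variable genes, with 80.2% of the variance, separated cholesterol from control libraries. The second (7.07%) separated libraries with siAtf3 (4.94 to 13.9) from those without it (-13.4 to -7.25). The 4 libraries with siNfe2l1 and cholesterol were spread along the first component from 24.04 to 40.5. Those with scramble and cholesterol lay between 37.1 and 43.6. Those with siAtf3 and cholesterol lay between 29.45 and 35.24, and those with double silencing and cholesterol between 28.56 and 33.71.

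**Figure D1:**
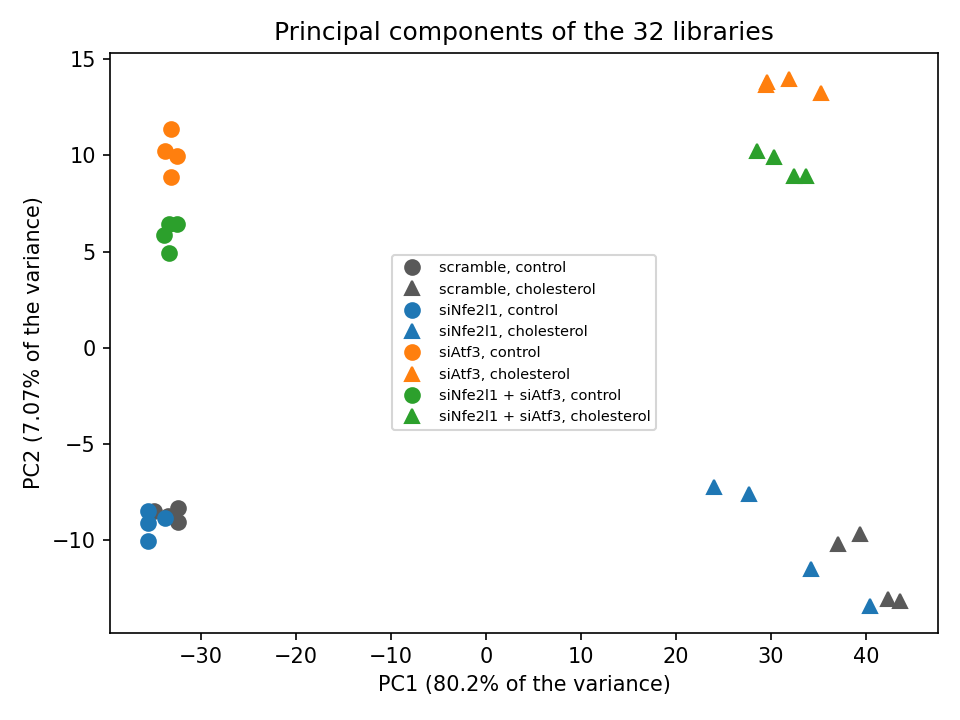
Scores of the 32 libraries on the first principal component (80.2% of the variance) and the second (7.07%); circles are control libraries, triangles cholesterol libraries, and colours the siRNA. Cholesterol libraries lie above 24 on the first component and control libraries below -32.

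Nfe2l1 mRNA (ENSMUSG00000038615, GRCm39 chromosome 11, 96708240 to 96720794, minus strand) fell from 486.8 ± 6.02 CPM with scramble to 73.8 ± 8.66 CPM with siNfe2l1 in control medium, and 15.1% was left (log2 fold change -2.72 ± 0.07, adjusted p = 1.01e-25). In cholesterol 14.7% was left, from 814.1 ± 43.3 to 120.0 ± 17.4 CPM (-2.76 ± 0.07). Double silencing left 23.4% in control medium and 19.3% in cholesterol, so that Nfe2l1 was higher with both siRNAs than with siNfe2l1 alone (0.63 ± 0.07, adjusted p = 6.11e-09 in control). Atf3 mRNA (ENSMUSG00000026628, chromosome 1, 190902493 to 190950236, minus strand) fell with siAtf3 from 26.8 ± 2.43 to 10.1 ± 0.78 CPM in control medium, with 37.8% left (-1.41 ± 0.31, adjusted p = 0.000796). In cholesterol it fell from 397.8 ± 129 to 40.9 ± 7.88 CPM, with 10.3% left (-3.28 ± 0.28). With double silencing 57.2% was left in control medium (15.3 ± 1.42 CPM, -0.80 ± 0.30, adjusted p = 0.0468) and 12.8% in cholesterol (-2.97 ± 0.28). The control call of double silencing was lost when any 1 of the 8 libraries compared was left out, at log2 fold changes from -0.86 to -0.75. Atf3 levels with siNfe2l1 alone did not pass the test against scramble. They were 31.8 ± 4.33 CPM in control medium (0.25, adjusted p = 0.744) and 267.8 ± 157 CPM in cholesterol (-0.57, adjusted p = 0.12).

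**Figure D2:**
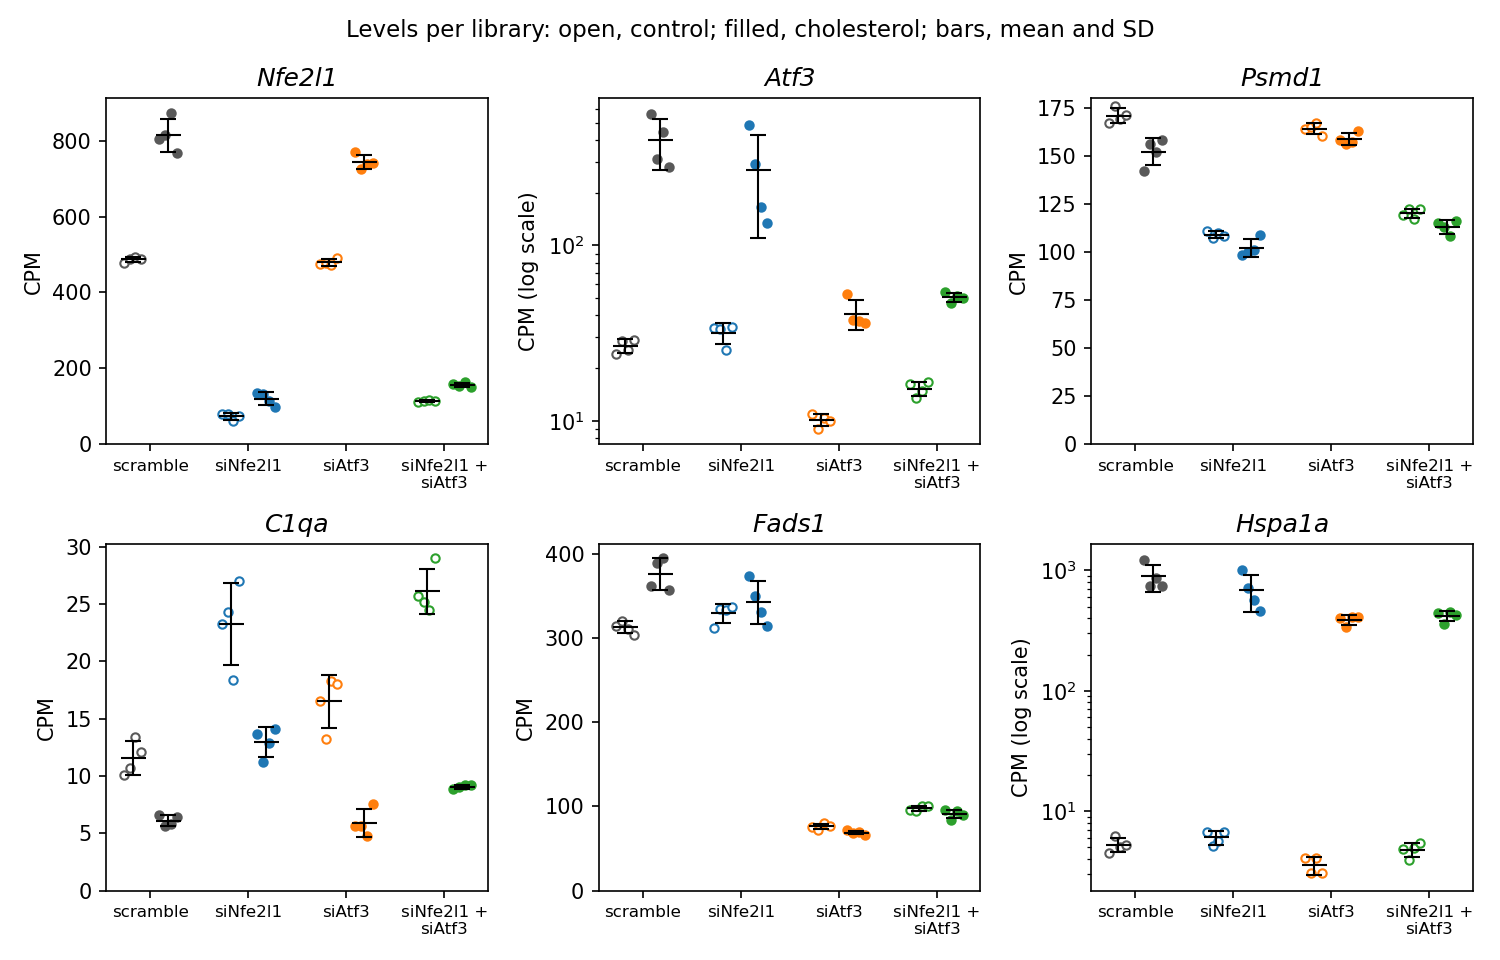
CPM of 6 genes in each of the 32 libraries by siRNA; open points are control and filled points cholesterol libraries, bars are mean and SD of 4, and the axes of Atf3 and Hspa1a are logarithmic. Nfe2l1 was left at 15.1% and 14.7% with siNfe2l1, and Atf3 was left at 37.8% and 10.3% with siAtf3.

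Cholesterol in scramble cells asked how adipocytes with both factors respond to loading. Among genes with an average log2 CPM of at least 2, the chaperone gene Hspa1a (ENSMUSG00000091971, chromosome 17, 35188166 to 35191132) went from 5.26 ± 0.69 to 889.1 ± 227 CPM (7.40 ± 0.24, adjusted p = 4.12e-19), the largest rise. Its near-identical neighbour Hspa1b rose by 6.36 ± 0.19, and the chemokine genes Cxcl2 and Cxcl1 rose by 7.20 ± 0.44 and 6.54 ± 0.34. Ecel1, of the endothelin-converting enzyme family, rose by 5.91 ± 0.25. Of the same genes Aplnr, the apelin receptor, fell most, from 19.8 ± 1.52 to 0.16 ± 0.07 CPM (-6.89 ± 0.21, adjusted p = 1.54e-24). It was followed by the endothelial lectin gene Clec14a (-5.42 ± 0.22), Sfrp2, a secreted Wnt-binding protein (-4.66 ± 0.13), the vasopressin receptor gene Avpr1a (-4.54 ± 0.15) and the protocadherin gene Pcdh17 (-4.21 ± 0.23). Cholesterol also raised Atf3 14.8-fold (3.89 ± 0.29) and Nfe2l1 1.67-fold (0.74 ± 0.07).

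Sterol genes moved in opposite directions by function. Of 25 genes of cholesterol synthesis and uptake, 20 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -0.57 (adjusted p = 5.08e-12; 0.0122 with an estimated correlation). The sterol carrier gene Stard4 fell by 2.19 ± 0.07. Of 14 LXR targets 10 rose and 0 fell (median 0.40, adjusted p = 0.000192), among them the sterol exporter gene Abcg1 (1.28 ± 0.05), Nr1h3, which encodes an LXR itself (1.32 ± 0.07), and the oxysterol-forming enzyme gene Ch25h (1.98 ± 0.10). The 13 fatty acid synthesis genes went both ways, with 8 higher and 4 lower (8 and 5 adjusted over the list alone), and the list did not pass (median 0.27, adjusted p = 0.64).

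Stress and inflammatory groups rose together. Of 20 genes of the integrated stress response 19 rose (median 1.63, adjusted p = 5.2e-15). Ddit3, a transcription factor of stressed cells, rose by 3.12 ± 0.19, with the amino acid genes Asns at 0.94 ± 0.05, Mthfd2 at 1.62 ± 0.08 and Slc7a5 at 1.55 ± 0.08. All 13 heat shock genes rose (median 1.88, adjusted p = 1.83e-20), as did 14 of 16 immediate early genes, with 1 lower (2.14, 3.71e-14), with Egr1 at 3.77 ± 0.12. Of 23 cytokine and NF-kB genes 17 rose and 2 fell (1.78, adjusted p = 1.95e-10). The feedback inhibitor gene Tnfaip3 was up by 3.03 ± 0.09, the monocyte chemokine gene Ccl2 by 1.85 ± 0.20 and Il6 by 2.43 ± 0.22. Of 18 antioxidant NFE2L2 targets 14 rose (0.53, adjusted p = 3.39e-11), with the haem oxygenase gene Hmox1 at 3.25 ± 0.10 and the thioredoxin reductase gene Txnrd1 at 1.76 ± 0.05. These 5 lists also passed with an estimated correlation (highest adjusted p = 0.0422). Chaperones of the endoplasmic reticulum had 10 higher and 4 lower of 17 (10 and 5 adjusted over the list alone), with Hspa5 at 1.27 ± 0.05 and Pdia4 at -0.54 ± 0.04 (median 0.21, adjusted p = 0.0209, and adjusted p = 0.194 with an estimated correlation). The interferon list fell, with 12 of 18 genes lower and 1 higher (-0.57, adjusted p = 0.0209, and adjusted p = 0.526 with an estimated correlation). Stat2, a transcription factor of that response, fell by 1.87 ± 0.18.

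Other lists moved less or rested on fewer genes. Of 33 proteasome subunits 11 rose and 4 fell (median 0.06, adjusted p = 0.253), and of 6 metallothionein and metal genes 3 rose, Mt1 among them (1.09 ± 0.11), and 3 fell (0.40, adjusted p = 0.511). The p53 list had 9 higher and 2 lower of 15 (0.23, adjusted p = 0.0421, and adjusted p = 0.318 with an estimated correlation), with Mdm2, whose product degrades p53, at 1.69 ± 0.09. Without scramble cholesterol library 1 the adjusted p of the list was 0.0635. Lysosome and autophagy genes had 10 higher and 2 lower of 16 (0.14, adjusted p = 0.0209, and adjusted p = 0.318 with an estimated correlation), with the autophagy receptor gene Sqstm1 at 2.30 ± 0.10. Of 10 thermogenic genes 7 rose and 2 fell (0.73, adjusted p = 0.0459, and adjusted p = 0.194 with an estimated correlation), with Ucp1, the uncoupling protein of brown fat, at 1.92 ± 0.14. That call was lost without scramble control library 4 (adjusted p = 0.0515) or scramble cholesterol library 2 (adjusted p = 0.0502). Of 13 mitochondrially encoded mRNAs 3 fell (2 adjusted over the list alone; -0.20, adjusted p = 0.409).

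Cell type markers parted in the same libraries. Of 20 adipocyte genes 18 rose and 1 fell (median 0.49, adjusted p = 5.29e-05), with the lipid droplet gene Cidec at 1.23 ± 0.06 and the glucose transporter gene Slc2a4 at 0.85 ± 0.05. Of 12 fibroblast markers 11 fell and 0 rose (-1.07, adjusted p = 1.94e-14), with the collagen genes Col1a2 at -1.62 ± 0.04 and Col3a1 at -1.97 ± 0.06. All 10 proliferation genes fell (-1.65, adjusted p = 3.31e-08), with the topoisomerase gene Top2a at -1.71 ± 0.09. These lists passed with an estimated correlation as well (highest adjusted p = 0.0414). Macrophage markers were lower in 11 of 13 genes (11, with 1 higher, adjusted over the list alone; -0.85, adjusted p = 0.00416, and adjusted p = 0.271 with an estimated correlation). Endothelial markers were lower in 8 of 10 and higher in 1 (-0.58, adjusted p = 0.00871, and adjusted p = 0.217 with an estimated correlation). Smooth muscle markers were lower in 6 of 10 and higher in 3 (-0.88, adjusted p = 0.049, and adjusted p = 0.183 with an estimated correlation). The smooth muscle call was lost without scramble cholesterol library 1 (adjusted p = 0.0529), 2 (adjusted p = 0.0505) or 4 (adjusted p = 0.0647). In edgeR 5584 genes rose and 5487 fell, 3167 of them more than 2-fold. With library totals in place of TMM, 4332 were higher and 6804 lower, and the median of all genes moved from 0.00 to -0.12.

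**Figure D3:**
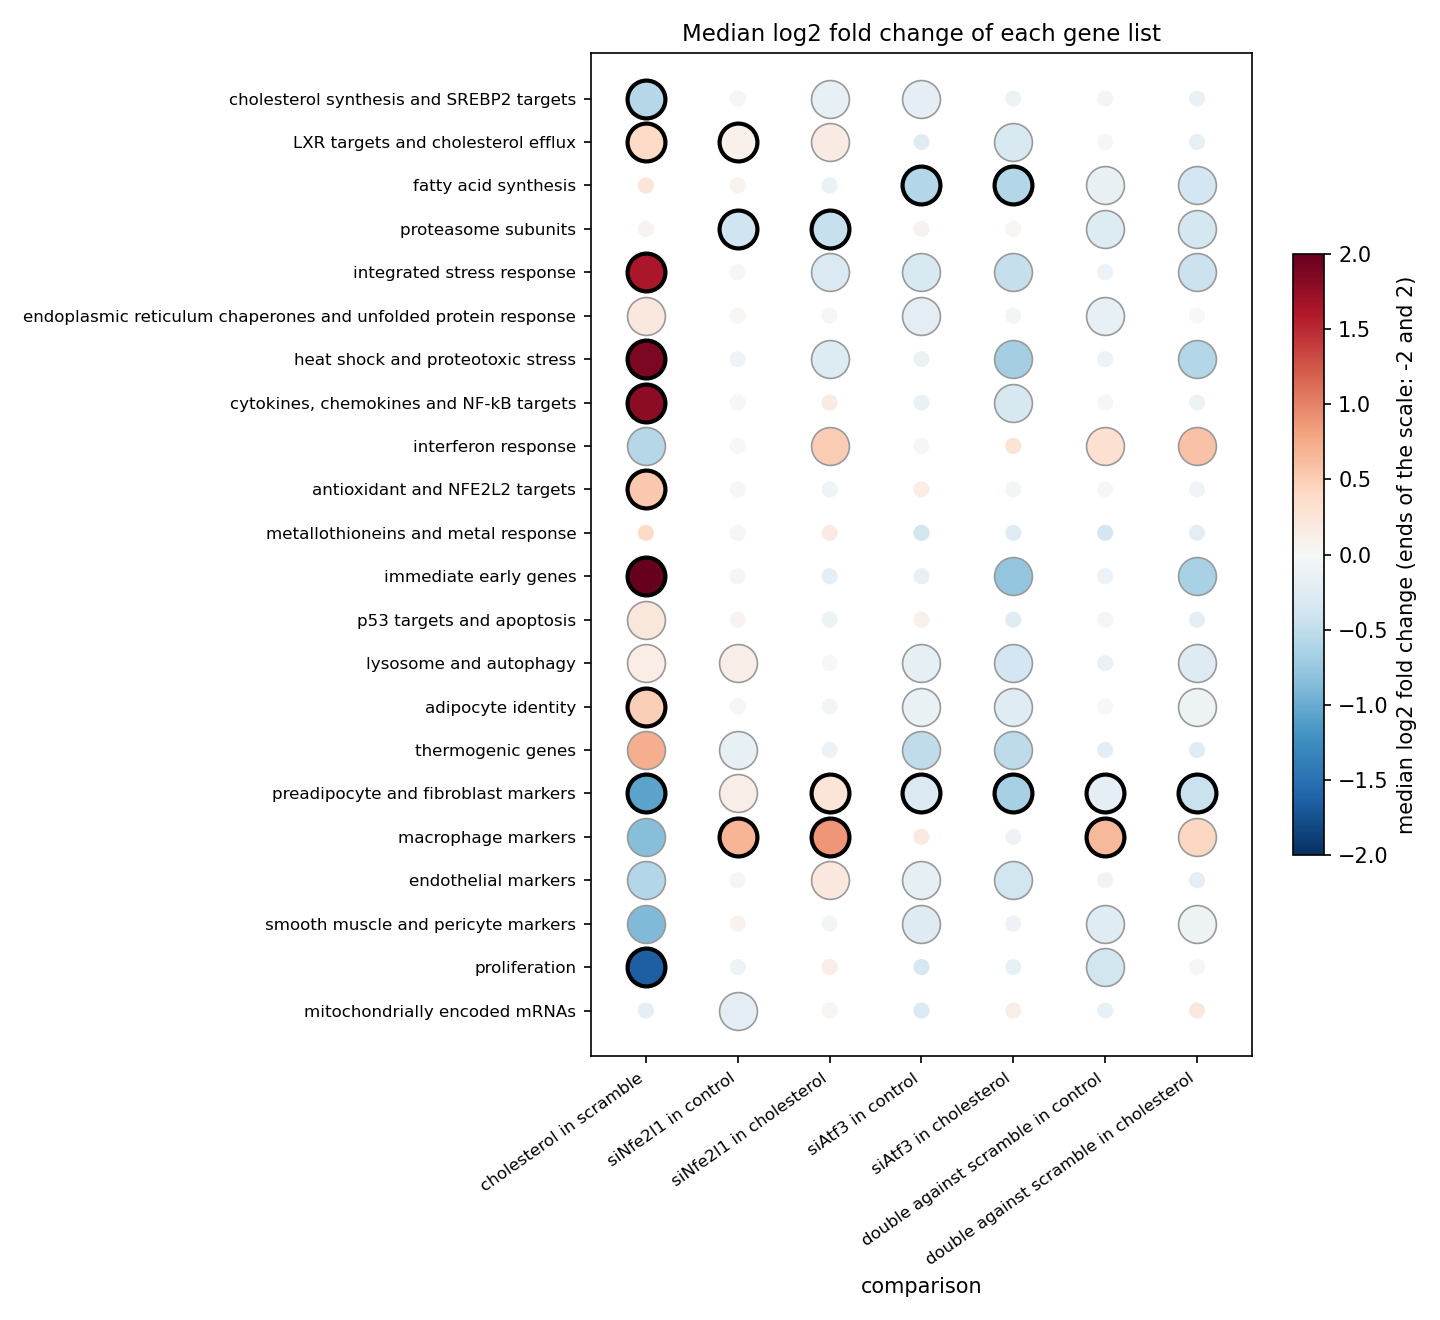
Median log2 fold change of 22 gene lists (vertical) in 7 comparisons (horizontal), with colour from -2 (blue) to 2 (red). Large circles passed the list test at adjusted p of 0.05, a black rim marks those that also passed with an estimated correlation, and small circles did not pass; 10 lists carry a black rim for cholesterol in scramble cells.

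Silencing Nfe2l1 in control medium asked what the factor maintains in unloaded adipocytes. Proteasome subunits fell as a group: 31 of 33 were lower and 0 higher (32 lower adjusted over the list alone), with a median of -0.41 (adjusted p = 1.01e-101; 0.000109 with an estimated correlation). Psmd1, of the regulatory particle (ENSMUSG00000026229, chromosome 1, 85992109 to 86066873), fell from 170.6 ± 3.69 to 109.1 ± 1.89 CPM (-0.64 ± 0.04, adjusted p = 6.2e-14). Psmd2 fell by 0.49 ± 0.03, Psma1 of the core particle by 0.62 ± 0.05 and the catalytic subunit gene Psmb5 by 0.39 ± 0.06. Among the lowest genes were Ucp1 (-1.09 ± 0.18), Ccdc152 (-1.19 ± 0.10, adjusted p = 5.09e-11), Nol3, an inhibitor of cell death (-1.03 ± 0.12), and the arginine methyltransferase gene Prmt5 (-1.11 ± 0.04), whose 3′ UTR holds the siNfe2l1 word AAAGCGA.

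Macrophage markers rose in the same libraries: 11 of 13 genes were higher and 0 lower (12 higher adjusted over the list alone), with a median of 0.68 (adjusted p = 1.21e-28; 0.000426 with an estimated correlation). The complement gene C1qa (ENSMUSG00000036887, chromosome 4, 136623228 to 136626114) went from 11.6 ± 1.48 to 23.3 ± 3.59 CPM (1.00 ± 0.11, adjusted p = 1.06e-07), C1qb rose by 0.90 ± 0.10, and Cd68, a lysosomal protein of macrophages, by 0.61 ± 0.08. Other genes among the highest were Cd5l, which macrophages secrete (0.95 ± 0.18), Wfdc17 (0.91 ± 0.16), Ms4a7 (0.91 ± 0.17) and Hephl1, of the ferroxidase family (0.99 ± 0.12). LXR targets rose slightly, with 4 of 14 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.00209; 0.00676 with an estimated correlation). They were led by the lipid carrier genes Pltp (0.41 ± 0.06) and Apoe (0.36 ± 0.07), which macrophages also express. Lysosome genes had 5 higher and 1 lower of 16 (9 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.00209, and adjusted p = 0.343 with an estimated correlation). Fibroblast markers had 3 of 12 higher (5 adjusted over the list alone; 0.13, adjusted p = 0.00673, and adjusted p = 0.0682 with an estimated correlation). Thermogenic genes (-0.17, adjusted p = 0.134 with an estimated correlation) and mitochondrially encoded mRNAs (-0.21, adjusted p = 0.708 with an estimated correlation) were called lower at the preset correlation. The call of the mitochondrial list was lost without scramble control library 1 (adjusted p = 0.0537) or siNfe2l1 control library 1 (adjusted p = 0.0522). Cytokine genes did not pass (2 higher and 1 lower of 23, 3 and 1 adjusted over the list alone; median -0.03, adjusted p = 0.973). In all, 531 genes rose and 487 fell, 25 of them more than 2-fold. The siNfe2l1 word was in the 3′ UTR of 7.92% of the lower genes searched, 0.671% of the higher ones and 2.42% of those not called. The word was chosen in this comparison. These shares and its z here (-7.92, the lowest of all words) are therefore not independent support for it. It also had the lowest z with siNfe2l1 in cholesterol (-4.81). With double silencing against scramble it did not pass in control medium (-1.86) or cholesterol (-1.14).

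Nfe2l1 silencing in cholesterol asked the same of loaded cells. Proteasome subunits were again lower, 32 of 33 (33 adjusted over the list alone), with a median of -0.46 (adjusted p = 4.23e-75; 0.000974 with an estimated correlation). Psmd2 fell by 0.48 ± 0.03, Psmc1 by 0.63 ± 0.05 and Psmb5 by 0.53 ± 0.06. Macrophage markers were higher in 12 of 13 genes (median 0.88, adjusted p = 7.06e-22; 0.00214 with an estimated correlation). Endothelial markers were higher in 5 of 10 (7 adjusted over the list alone; 0.20, adjusted p = 0.00167, and adjusted p = 0.320 with an estimated correlation). Adgre1, which encodes the macrophage antigen F4/80, stood at 1.19 ± 0.12 and C1qa at 1.09 ± 0.13. The complement receptor gene C5ar1 and the B cell and myeloid receptor gene Cd180 stood at 1.68 each (± 0.27 and ± 0.21). Lowest apart from Nfe2l1 were the myosin gene Myh14 (-1.16 ± 0.11), Nol3 (-1.14 ± 0.12) and Ucp1 (-1.09 ± 0.14). Fibroblast markers rose in 6 of 12 genes (0.27, adjusted p = 0.000231; 0.0149 with an estimated correlation), for example Col1a2 by 0.28 ± 0.04.

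Inflammatory genes were examined in loaded cells with siNfe2l1 because the study's title names adipocyte inflammation. Of 23 cytokine genes 6 were higher and 0 lower, and the list did not pass (median 0.16, adjusted p = 0.0942). Ccl2 (203.2 ± 36.6 against 198.2 ± 47.3 CPM) and Il6 (29.6 ± 7.87 against 33.9 ± 7.39 CPM) did not pass either (adjusted p = 0.92 and 0.522). Interferon genes were higher, 11 of 18 (12 adjusted over the list alone; median 0.50, adjusted p = 3.87e-06, and adjusted p = 0.365 with an estimated correlation). The transcription factor gene Irf9 stood at 0.57 ± 0.08 and Oasl2 at 0.82 ± 0.14. Genes of the integrated stress response were lower in 5 of 20 (10 adjusted over the list alone; -0.29, adjusted p = 0.000231, and adjusted p = 0.389 with an estimated correlation). Heat shock genes were lower in 3 of 13 (10 adjusted over the list alone; -0.27, adjusted p = 0.000629, and adjusted p = 0.389 with an estimated correlation). Cholesterol synthesis genes were lower in 9 of 25 and higher in 1 (10 and 2 adjusted over the list alone; -0.16, adjusted p = 0.00169, and adjusted p = 0.365 with an estimated correlation). Mvd, an early enzyme of the pathway, stood at -0.58 ± 0.10. The interferon, integrated stress, heat shock and fibroblast lists thus moved against the cholesterol response. On the first principal component siNfe2l1 cholesterol libraries 3 and 4 lay at 27.73 and 24.04, below libraries 1 and 2 (40.48 and 34.25), and a weaker response of those 2 libraries was not separated from an effect of siNfe2l1. edgeR called 1923 genes higher and 1459 lower, 3382 in all, 193 of them over 2-fold. With only these 2 groups in the fit 645 genes were called, and without siNfe2l1 cholesterol library 3 the number was 2153. With library totals 2615 were higher and 992 lower.

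**Figure D4:**
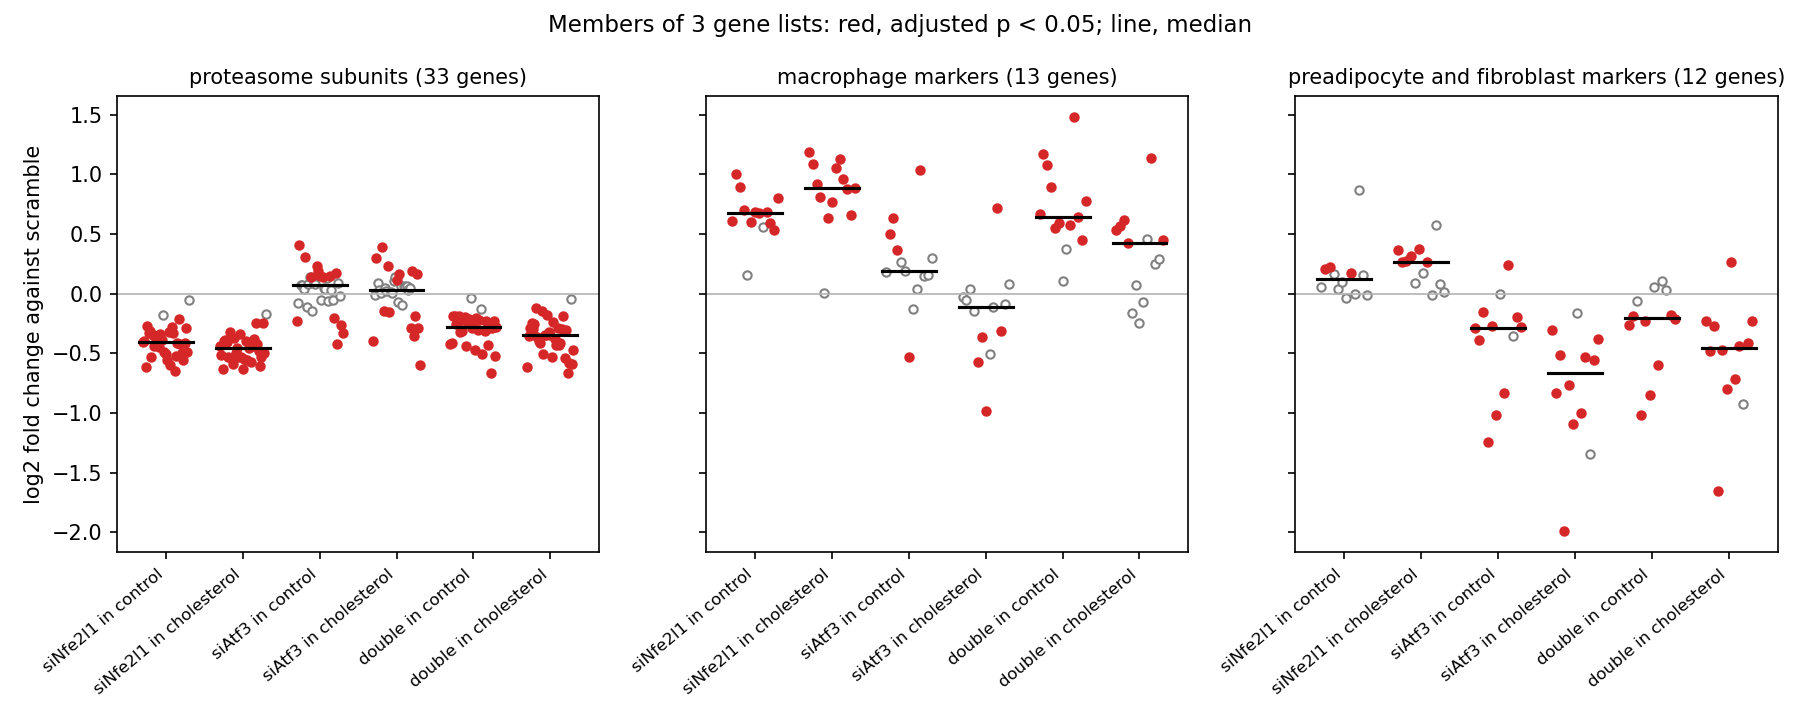
Log2 fold change against scramble of each member of the proteasome, macrophage and fibroblast lists in 6 comparisons; red points passed the gene test at adjusted p of 0.05, open points did not, and lines are medians. Proteasome medians lie at -0.41 and -0.46 with siNfe2l1 and at -0.28 and -0.35 with double silencing.

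Silencing Atf3 in control medium asked what the factor maintains where its own level is low. Fatty acid synthesis fell: 9 of 13 genes were lower and 0 higher (11 lower adjusted over the list alone), with a median of -0.58 (adjusted p = 1.04e-20; 0.00471 with an estimated correlation). The desaturase gene Fads1 (ENSMUSG00000010663, chromosome 19, 10160252 to 10174241) went from 312.8 ± 7.17 to 76.3 ± 3.21 CPM (-2.04 ± 0.05, adjusted p = 1.24e-26). Acly, which makes cytosolic acetyl-CoA, fell by 1.44 ± 0.06 and the elongase gene Elovl6 by 1.16 ± 0.07. The 3′ UTRs of 3 of the 9 lower members, Fads1 among them, hold a siAtf3 word. Fibroblast markers fell in 9 of 12 genes and rose in 1 (-0.28, adjusted p = 4.49e-06; 0.00471 with an estimated correlation). Col3a1 (-1.24 ± 0.06) and Fbn1 (-1.02 ± 0.08) hold a siAtf3 word, and Ly6a, a surface antigen of precursor cells, fell by 0.83 ± 0.05 without one.

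Among the highest were the metabolic enzyme gene Ogdhl (2.50 ± 0.12), the myeloid lectin gene Clec4n (1.81 ± 0.17), Aldh1a1, which makes retinoic acid (1.79 ± 0.07), and Cd5l (1.61 ± 0.18). Mup17, 1 of a cluster of near-identical genes, stood at 3.68 ± 0.58. Lowest were the actin gene Acta1 (-2.70 ± 0.26), the haptoglobin gene Hp (-2.20 ± 0.13), the calcium pump gene Atp2b4 (-2.07 ± 0.11) and Ube2v2 (-2.07 ± 0.16), and each of these 4 holds a siAtf3 word. The linker histone gene H1f4 fell by 2.05 ± 0.12 and holds no siAtf3 word.

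Further lists were lower in unloaded siAtf3 cells, with calls lost when the correlation was estimated. Cholesterol synthesis genes fell in 13 of 25 and rose in 1 (14 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.000562, and adjusted p = 0.247 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 12 of 17 and rose in 1 (13 and 1 adjusted over the list alone; -0.21, adjusted p = 0.00135, and adjusted p = 0.108 with an estimated correlation), with Manf at -0.56 ± 0.06. Adipocyte genes fell in 10 of 20 and rose in 2 (10 and 3 adjusted over the list alone; -0.13, adjusted p = 0.000208, and adjusted p = 0.106 with an estimated correlation). Gpd1, which makes glycerol phosphate for fat, stood at -1.28 ± 0.05 and Adipoq at -0.37 ± 0.04. Thermogenic genes fell in 6 of 10 (-0.50, adjusted p = 0.00514, and adjusted p = 0.106 with an estimated correlation), and the deiodinase gene Dio2 (-2.03 ± 0.18) holds a siAtf3 word. Integrated stress genes fell in 10 of 20 (11 adjusted over the list alone; -0.32, adjusted p = 0.00321, and adjusted p = 0.482 with an estimated correlation). Lysosome genes fell in 9 of 16 and rose in 1 (-0.18, adjusted p = 0.00956, and adjusted p = 0.463 with an estimated correlation), where the protease gene Ctsb (-1.01 ± 0.04) holds a siAtf3 word. Smooth muscle markers fell in 5 of 10 and rose in 1 (-0.25, adjusted p = 0.0183, and adjusted p = 0.108 with an estimated correlation), and the macrophage list did not pass although Lyz2 rose by 1.04 ± 0.14.

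In unloaded cells siAtf3 raised 3071 genes and lowered 3093, 508 by more than 2-fold. With library totals 5913 were higher and 1871 lower, and the median of all genes moved from 0.01 to 0.15. The siAtf3 words GTCAACA, GGACGAC and CACCGGA were in the 3′ UTR of 1100 of 10837 genes: they were found in 541 of 2579 lower genes (20.98%), in 5.08% of the higher genes and in 7.52% of those not called. Of the 131 genes searched that were lower over 2-fold, 56 held a word (42.75%). The words were chosen in this comparison, so these shares are not independent support for them.

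Atf3 silencing in cholesterol asked what the induced factor contributes under loading. Fads1 (-2.45 ± 0.05, adjusted p = 3.68e-29), the secreted protease gene Htra1 (-2.39 ± 0.05), the transcriptional coactivator gene Ppargc1a (-2.48 ± 0.19) and Wscd2 (-2.38 ± 0.16) fell most apart from Atf3, and all hold a siAtf3 word. Aldh1a1 (2.26 ± 0.07), Ogdhl (2.40 ± 0.12) and Klhl23 (2.48 ± 0.18), which holds a siAtf3 word, were among the highest. Fibroblast markers fell in 10 of 12 genes (11 adjusted over the list alone; median -0.66, adjusted p = 3.27e-13; 2.46e-05 with an estimated correlation). Col3a1 (ENSMUSG00000026043, chromosome 1, 45350698 to 45388866) went from 1872 ± 86.5 to 470.8 ± 46.9 CPM (-1.99 ± 0.06). Fatty acid synthesis fell in 10 of 13 genes (-0.59, adjusted p = 2.19e-14; 0.0255 with an estimated correlation), with Acly at -1.63 ± 0.06.

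Stress and inflammatory genes that cholesterol had raised were lower with siAtf3 in loaded cells, and each of these list calls was lost with an estimated correlation. All libraries with siAtf3 and cholesterol lay below those with scramble and cholesterol on the first principal component (29.45 to 35.24 against 37.1 to 43.59). A weaker response as a whole was not separated from an effect on these genes. Fibroblast markers, which cholesterol had lowered, were lower still with siAtf3. Heat shock genes fell in 12 of 13 (13 adjusted over the list alone; median -0.68, adjusted p = 2.33e-06, and adjusted p = 0.206 with an estimated correlation). The chaperone genes Hsph1 stood at -1.15 ± 0.11 and Hspb1 at -1.59 ± 0.15. Immediate early genes fell in 15 of 16 (-0.78, adjusted p = 7.03e-05, and adjusted p = 0.268 with an estimated correlation), with Jund at -0.99 ± 0.14. Integrated stress genes fell in 16 of 20 and rose in 1 (17 and 1 adjusted over the list alone; -0.47, adjusted p = 0.000454, and adjusted p = 0.438 with an estimated correlation), among them Ddit3 (-1.02 ± 0.17), which holds a siAtf3 word. Cytokine genes fell in 12 of 23 and rose in 1 (13 and 1 adjusted over the list alone; -0.34, adjusted p = 0.00993, and adjusted p = 0.522 with an estimated correlation). Lcn2, an iron-binding inflammatory protein, stood at -1.59 ± 0.15, Ccl2 at -0.69 ± 0.19 and Il6 at -0.93 ± 0.20. Lysosome genes fell in 14 of 16 and rose in 1 (-0.36, adjusted p = 3.17e-06, and adjusted p = 0.114 with an estimated correlation). Adipocyte genes fell in 12 of 20 and rose in 2 (12 and 3 adjusted over the list alone; -0.24, adjusted p = 0.000476, and adjusted p = 0.114 with an estimated correlation), and endothelial markers in 8 of 10 (-0.38, adjusted p = 0.0055, and adjusted p = 0.264 with an estimated correlation).

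Sterol genes were mixed in loaded siAtf3 cells: Hmgcs1, of cholesterol synthesis, was higher (0.65 ± 0.06), and the thiolase gene Acat2 was lower (-0.82 ± 0.07). LXR targets were lower in 10 of 14 and higher in 3 (-0.33, adjusted p = 0.0288, and adjusted p = 0.114 with an estimated correlation), a call lost without siAtf3 cholesterol library 1 (adjusted p = 0.0583). Pltp fell by 0.76 ± 0.06 and Abcg1 rose by 0.59 ± 0.05. edgeR called 3898 genes higher and 4659 lower, 1029 of them over 2-fold. With library totals 6707 were higher and 2712 lower, and the median of all genes moved from -0.02 to 0.17. A siAtf3 word was in 15.2% of the lower genes searched.

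Adding siAtf3 to siNfe2l1 asked whether Atf3 loss alters the state of Nfe2l1-silenced cells. In control medium proteasome subunits rose in 12 of 33 genes and fell in 1 (14 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.00086, and adjusted p = 0.768 with an estimated correlation). Psma1 rose by 0.43 ± 0.05 and Psma5 by 0.34 ± 0.05, in libraries in which Nfe2l1 itself was higher by 0.63 ± 0.07. Fibroblast markers fell in 9 of 12 genes (10 adjusted over the list alone; -0.33, adjusted p = 3.52e-10; 0.000142 with an estimated correlation). Smooth muscle markers fell in 6 of 10 and rose in 1 (7 and 1 adjusted over the list alone; -0.44, adjusted p = 0.000986; 0.0488 with an estimated correlation). Ogdhl (1.80 ± 0.12) and Pck1, an enzyme of glyceroneogenesis (1.53 ± 0.14), were among the highest, and Acta1 (-2.94 ± 0.25), Hephl1 (-2.02 ± 0.13) and Fads1 (-1.75 ± 0.05) among the lowest, of which Acta1 and Fads1 hold a siAtf3 word. Fatty acid genes fell in 6 of 13 (-0.12, adjusted p = 2.76e-09, and adjusted p = 0.0715 with an estimated correlation). edgeR called 2092 genes higher and 2462 lower, and with library totals 4158 and 1523, with a median of all genes of 0.10 in place of 0.01.

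In cholesterol the same addition lowered 11 of 12 fibroblast markers (median -0.58, adjusted p = 1.48e-20; 3.41e-07 with an estimated correlation), with Col3a1 at -1.97 ± 0.06. Macrophage markers fell in 11 of 13 genes (-0.52, adjusted p = 0.000502, and adjusted p = 0.307 with an estimated correlation), with Cd68 at -0.56 ± 0.08 and Adgre1 at -0.66 ± 0.12. Proteasome subunits rose in 17 of 33 and fell in 3 (18 and 3 adjusted over the list alone; 0.15, adjusted p = 0.00309, and adjusted p = 0.612 with an estimated correlation). Psma5 stood at 0.41 ± 0.05. Cytokine genes fell in 10 of 23 and rose in 1 (11 and 1 adjusted over the list alone; -0.25, adjusted p = 0.0179, and adjusted p = 0.573 with an estimated correlation). Lcn2 stood at -1.08 ± 0.14, while Il6 passed only without double silencing cholesterol library 3 (-0.35 ± 0.19, adjusted p = 0.171 with it and 0.0169 without it). Heat shock genes fell in 10 of 13 (-0.38, adjusted p = 0.00226, and adjusted p = 0.498 with an estimated correlation). Aldh1a1 rose by 1.73 ± 0.07, and the parathyroid hormone receptor gene Pth1r fell by 1.98 ± 0.09. edgeR called 2672 genes higher and 3547 lower, and with library totals 4523 and 2312.

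Double silencing against scramble asked what the loss of both factors does. In control medium 31 of 33 proteasome subunits fell (32 adjusted over the list alone; median -0.28, adjusted p = 8.84e-18, and adjusted p = 0.136 with an estimated correlation). Psmd3 stood at -0.66 ± 0.05 and Psmd1 at -0.51 ± 0.04. Macrophage markers rose in 11 of 13 (12 adjusted over the list alone; 0.65, adjusted p = 9.64e-13; 0.0303 with an estimated correlation). C1qa stood at 1.17 ± 0.11, and Cd5l (2.09 ± 0.18) and Clec4n (2.08 ± 0.17) were among the highest genes. Fibroblast markers fell in 8 of 12 (-0.20, adjusted p = 1.02e-05; 0.00993 with an estimated correlation). Fatty acid genes fell in 7 of 13 (-0.15, adjusted p = 6.2e-07, and adjusted p = 0.141 with an estimated correlation). Fads1 stood at -1.67 ± 0.05. edgeR called 2199 genes higher and 2426 lower, and with library totals 4373 and 1473, with a median of all genes of 0.11 in place of 0.01.

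In cholesterol 32 of 33 proteasome subunits fell with double silencing (median -0.35, adjusted p = 4.11e-15, and adjusted p = 0.219 with an estimated correlation), with Psmd3 at -0.67 ± 0.05. Fibroblast markers fell in 10 of 12 and rose in 1 (-0.45, adjusted p = 1.12e-08; 0.00058 with an estimated correlation). Heat shock genes fell in 12 of 13 (13 adjusted over the list alone; -0.59, adjusted p = 1.14e-06, and adjusted p = 0.219 with an estimated correlation). Interferon genes rose in 13 of 18 and fell in 2 (0.58, adjusted p = 0.000787, and adjusted p = 0.43 with an estimated correlation). Macrophage markers rose in 6 of 13 (0.42, adjusted p = 0.0192, and adjusted p = 0.43 with an estimated correlation). Irf9 rose by 0.80 ± 0.08 and Irf7 fell by 0.70 ± 0.07. Cytokine genes had 2 higher and 9 lower of 23 and did not pass (-0.10, adjusted p = 0.318). On the first principal component the double silencing cholesterol libraries lay below those with scramble (28.56 to 33.71 against 37.1 to 43.59). For the lower heat shock genes, a weaker response as a whole was not separated from an effect on these genes. edgeR called 3537 genes higher and 4056 lower, and with library totals 6049 and 2299, with a median of all genes of 0.14 in place of -0.01.

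Cholesterol was also compared with control medium within each silenced state. Atf3 rose 8.40-fold with siNfe2l1 (3.07 log2) and 4.03-fold with siAtf3 (2.01). Cxcl2 rose by 6.91, 6.32 and 6.59 and Hspa1a by 6.82 ± 0.23, 6.77 ± 0.24 and 6.44 ± 0.23 with siNfe2l1, siAtf3 and double silencing. Aplnr fell in all 3 states, by 5.01 ± 0.17, 5.67 ± 0.21 and 5.13 ± 0.18. Cholesterol synthesis genes fell in 24, 20 and 21 of 25 (22 adjusted over the list alone in the last), with medians of -0.81, -0.43 and -0.64 (highest adjusted p with an estimated correlation 0.0246). All 13 heat shock genes rose in each state (medians 1.64, 1.15 and 1.26), cytokine genes rose in 17, 17 and 18 of 23, and all 12 fibroblast markers and all 10 proliferation genes fell in each. Macrophage markers fell in 11 of 13 with siNfe2l1 (-0.59, adjusted p = 0.332 with an estimated correlation). They fell in 13 of 13 with siAtf3 and with double silencing (-1.24 and -1.20, adjusted p = 0.0477 and 0.0457 with an estimated correlation). edgeR called 10206 genes with siNfe2l1, 9860 with siAtf3 and 9964 with double silencing.

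Interactions tested whether the cholesterol response itself differed between siRNAs. With siNfe2l1 the immediate early genes Egr3 (1.10 ± 0.15) and Egr2 (0.75 ± 0.11, adjusted p = 0.000279 for both) differed. Egr2 went from 32.3 ± 1.74 to 22.8 ± 2.84 CPM with scramble and from 29.4 ± 0.64 to 35.1 ± 4.25 CPM with siNfe2l1. edgeR called 42 genes in all, 35 higher and 7 lower. That number was moved more than 1.5-fold by 15 of the 16 libraries left out in turn, from 2 genes without scramble control library 4, siNfe2l1 control library 2 or siNfe2l1 control library 4 to 1337 genes without siNfe2l1 cholesterol library 1. Left out singly, scramble control libraries 1 to 3 gave 9, 10 and 11 genes, siNfe2l1 control libraries 1 and 3 gave 87 and 23, and scramble cholesterol libraries 1 to 4 gave 10, 27, 5 and 188. Without siNfe2l1 cholesterol library 3 or 4 the numbers were 4 and 6. DESeq2 called 344 genes, and edgeR on these 4 groups alone 2. Of the 22 lists 14 were called, 5 higher and 9 lower, and 0 held with an estimated correlation. Interferon genes had the smallest adjusted p (1 of 18 higher, 9 and 1 lower adjusted over the list alone; median 0.44, adjusted p = 3.53e-07, and adjusted p = 0.284 with an estimated correlation). Integrated stress genes (0 of 20 called; -0.30, adjusted p = 6.23e-05, and adjusted p = 0.394 with an estimated correlation) and cholesterol synthesis genes (1 of 25 lower, 7 and 2 higher adjusted over the list alone; -0.16, adjusted p = 6.23e-05, and adjusted p = 0.284 with an estimated correlation) were lower. The cytokine list did not pass (0 genes called, 2 higher adjusted over the list alone, median 0.11, adjusted p = 0.0927), and neither did Ccl2 and Il6 (adjusted p = 0.831 and 0.955).

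With siAtf3 the sterol response was weaker at some genes, with interactions of 0.81 ± 0.10 at Stard4 and 0.67 ± 0.08 at Hmgcs1. Abcg1, which cholesterol raised, rose less on the log2 scale (-0.52 ± 0.08). It went from 265.2 ± 10.5 to 449.9 ± 20.7 CPM with siAtf3 and from 123.1 ± 7.21 to 298.7 ± 20.7 CPM with scramble. Its level in control medium was thus already higher with siAtf3, and in CPM its rise was not smaller. Fibroblast markers fell further in cholesterol with siAtf3 (6 of 12 genes, 7 adjusted over the list alone; median -0.36, adjusted p = 1.4e-07; 0.00136 with an estimated correlation), with Col3a1 at -0.76 ± 0.08. Heat shock genes rose less (11 of 13; -0.53, adjusted p = 7.09e-09, and adjusted p = 0.188 with an estimated correlation). So did immediate early genes (10 of 16, 11 adjusted over the list alone; -0.57, adjusted p = 2.23e-06, and adjusted p = 0.188 with an estimated correlation). Among single genes Rasd1, a small G protein, was among the highest (1.96 ± 0.20), and Crocc2 (-1.97 ± 0.26) and the nuclear receptor gene Nr4a3 (-1.82 ± 0.30) were among the lowest. edgeR called 1054 genes higher and 1551 lower, and with library totals 1321 and 1228. For double silencing the interaction was -0.63 ± 0.08 at Col3a1, with 1107 genes higher and 1224 lower, and with library totals 1474 and 982.

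The interaction of the siRNAs asked whether siAtf3 acted differently on Nfe2l1-silenced cells. In control medium fatty acid genes differed (6 of 13 higher, 10 adjusted over the list alone; median 0.31, adjusted p = 3.6e-18; 0.00858 with an estimated correlation). The loss of Acly with siAtf3 was smaller with siNfe2l1 present (0.78 ± 0.09, adjusted p = 1.26e-06) and that of Elovl6 too (0.63 ± 0.09). Atf3 itself fell less with siNfe2l1 present, by 1.05 ± 0.30 against 1.41 ± 0.31 in control medium and by 2.40 ± 0.27 against 3.28 ± 0.28 in cholesterol, a difference not called (adjusted p = 0.84 and 0.17). Nfe2l1 was silenced less with both siRNAs (0.65 ± 0.10 in control medium and 0.52 ± 0.09 in cholesterol). Smaller effects through weaker silencing were not separated from other causes. Adipocyte genes (4 of 20, 7 adjusted over the list alone; 0.18, adjusted p = 1.36e-08; 0.00876 with an estimated correlation) differed the same way. Thermogenic genes did too (3 of 10, 4 adjusted over the list alone; 0.38, adjusted p = 2.74e-07; 0.00466 with an estimated correlation), with Ucp1 at 1.53 ± 0.24 (adjusted p = 0.000199). In cholesterol Acly (0.90 ± 0.09, adjusted p = 2.78e-08) and Ucp1 (1.45 ± 0.20) differed as well. The fatty acid list again differed there (9 of 13, 12 adjusted over the list alone; 0.50, adjusted p = 1.84e-19; 0.0119 with an estimated correlation). edgeR called 232 genes higher and 96 lower in control medium. The total of 328 became 214 without siAtf3 control library 2, 557 with DESeq2 and 757 with only the 4 groups in the fit. In cholesterol 475 were higher and 390 lower. The cholesterol number, 865, was 2295 without siNfe2l1 cholesterol library 1, 510 without siNfe2l1 cholesterol library 3, 518 and 575 without siAtf3 cholesterol library 2 or 3, 559 without double silencing cholesterol library 1, 1337 with DESeq2 and 259 with only the 4 groups in the fit. With library totals it was 154 higher and 175 lower in control medium, and 262 and 966 in cholesterol.

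Whether siAtf3 reversed the changes made by siNfe2l1 was counted over genes called in both comparisons, in fits of the 3 groups concerned. In control medium 757 genes moved in opposite directions and 203 in the same direction: 422 rose with siNfe2l1 and fell when siAtf3 was added (149.7 by chance), and 335 fell and then rose (130.0 by chance). In cholesterol 510 moved in opposite directions and 148 in the same (779 and 333 with the replicate number as a block). Both comparisons share the siNfe2l1 libraries, which by itself gives a negative relation: across genes, which are not independent replicates, r was -0.27 in control medium, and simulated data without any effect gave -0.51. These values of r are not comparable, since real effects widen the spread of the changes and the simulation holds no effects. The covariance was -0.0205 in control medium against -0.0124 simulated (mean of 20), and -0.0162 in cholesterol against -0.0169 simulated. With the siNfe2l1 libraries divided so that 2 served each comparison, 431.2 genes on average moved in opposite and 165.8 in the same direction in control medium (r = -0.06). In cholesterol this gave on average 188.3 opposite and 232.5 the same (r = 0.01), but the 6 divisions ran from r = -0.17 to 0.27 and from 11 to 1188 genes in the same direction. Genes that rose and then fell (102.5, 66.02 by chance) and genes that fell and then rose (85.83, 64.91 by chance) still exceeded chance on average, as did genes that rose in both (88.33, 58.21 by chance) or fell in both (144.2, 73.55 by chance). Whether opposite genes outnumber the others in cholesterol was thus left open. Nfe2l1 itself was silenced less once siAtf3 was added, at 114 against 73.8 CPM in control medium and 156.8 against 120 CPM in cholesterol. Opposite movement through this weaker silencing was not separated from an effect of Atf3 loss.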

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

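The counts of other splits in this part were decided on only after the results had been seen, while the interaction tests and the search for libraries far from their group were planned.

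The 13 genes watched were tested in all 5 interactions, including those between the siRNAs. In edgeR 16 of these 65 tests passed, some of them at the silenced genes themselves. The cholesterol response differed between siRNAs at several of the genes watched. With siAtf3 the induction of Atf3 itself was smaller (interaction -1.88 ± 0.41, adjusted p = 0.00357). Hmox1 rose less (-0.49 ± 0.13, adjusted p = 0.00873). With double silencing the same genes differed, Atf3 by -2.17 ± 0.40 (adjusted p = 0.0012) and Hmox1 by -0.76 ± 0.13 (adjusted p = 0.000311). Nfe2l1 (-0.28 ± 0.09, adjusted p = 0.0431) and Ddit3 (-0.75 ± 0.25, adjusted p = 0.0493) also passed with double silencing, and each of these calls was lost in 14 of the 16 fits that left out 1 library.

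The effect of siAtf3 differed with siNfe2l1 present at Nfe2l1 itself, by 0.65 ± 0.10 in control medium (adjusted p = 7.14e-05) and 0.52 ± 0.09 in cholesterol (adjusted p = 0.000872). Hmox1 differed by 0.49 ± 0.13 in control medium (adjusted p = 0.0351, lost in 10 of 16 fits without 1 library) and by 0.54 ± 0.13 in cholesterol (adjusted p = 0.00995). In cholesterol the metallothionein gene Mt1 (0.55 ± 0.15, adjusted p = 0.0326, lost in 8 fits) passed as well.

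Across all genes edgeR called 42 in the interaction of siNfe2l1 with cholesterol, 2605 in that of siAtf3 with cholesterol, 2331 for double silencing with cholesterol, and 328 in control medium and 865 in cholesterol for the 2 siRNAs. Each was compared with 100 splits of its 16 libraries, fitted on those libraries alone. The additive effects of the siRNA and of cholesterol, or of the 2 siRNAs, were taken out first and limma was used. This form was chosen after splits of the values as counted had been seen, because those mix libraries that these effects set apart and nearly all call 0 genes. For siAtf3 with cholesterol (2759 genes, highest other 1) and for double silencing with cholesterol (2602 genes, highest other 1) only the real split of 100 gave as many, which speaks against chance. For the 2 siRNAs 1 of 100 splits, the real one, gave as many in control medium (752 genes, highest other 256), and 2 of 100 did in cholesterol (238 genes). Both shares speak against chance, although 1 other split in cholesterol called 555 genes, which points to a structure of the samples. For siNfe2l1 with cholesterol 3 of 100 gave as many as the real 2 genes of limma, with up to 20 in another split, which also points to such a structure. These splits do not weigh the 42 genes of edgeR. With the values as counted 5 of 100 gave as many as the real 2 genes, with up to 286 in another split. Of the other 4 of these, 0 kept a real pair of groups. For this interaction the weight against chance thus depends on how the splits were made. The values as counted gave 2 of 100 for siAtf3 with cholesterol and 4 of 100 for the 2 siRNAs in each medium. They gave 7 of 100 for double silencing with cholesterol, which alone would not speak against chance. All the other splits as large in these 4 kept a real pair of groups.

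In each of the 12 comparisons of 2 groups the real split of 8 libraries was the only 1 of 35 to give as many genes. This is the smallest share that 35 splits can give, so it speaks against chance without excluding it. The real counts ran from 645 (siNfe2l1 in cholesterol) to 10282 (cholesterol with double silencing) in these fits, and the highest other split had 1 gene.

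Single libraries lay far from the other 3 of their group in 8 of 112 checks of totals and watched genes, where chance gives about 5%. Total counts stood apart for siAtf3 control library 4 (24725327), double silencing control library 4 (33828418) and scramble cholesterol library 1 (24106078). Atf3 was 25.4 CPM in siNfe2l1 control library 3 (33.3 to 34.6 in the others) and 52.7 CPM in siAtf3 cholesterol library 1 (36.3 to 37.5). Hspa5 was 3097 CPM in scramble cholesterol library 1 (2648 to 2682), Ccl2 183.0 CPM in double silencing cholesterol library 3 (122.8 to 128.8) and Hmox1 655.9 CPM in double silencing control library 3 (726.6 to 733.1).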

How the results depend on the processing

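Scaling by library totals and the 2 settings that leave out several libraries were chosen after the data had been seen, the other alternatives before. The counts of the 12 comparisons of 2 groups stayed within 1.5-fold under every setting except for siNfe2l1 in cholesterol (3382), which gave 645 with only the groups compared in the fit and 2153 to 4755 with each library left out in turn. The interaction of siNfe2l1 with cholesterol (42 genes) gave 72 without a filter, 344 with DESeq2, 2 with only the groups compared and 143 with the replicate block. It gave 670 without the libraries numbered 1, 5 without scramble cholesterol library 1 and siNfe2l1 control library 4, and 2 to 1337 with each library left out in turn. The interaction of the siRNAs in control medium (328) gave 557 with DESeq2, 757 with only the groups compared, 537 without those 2 libraries and 214 to 339 with each library left out. In cholesterol (865) it gave 1337 with DESeq2, 259 with only the groups compared, 1605 without the libraries numbered 1 and 510 to 2295 with each library left out. The cause was not tested where the number of libraries stayed the same.

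Of 1495 log2 fold changes of named genes, 1396 of them called, the same side of the threshold was kept by 1492 with DESeq2 size factors, 1488 with DESeq2, 1486 with the replicate block, and 1472 with limma-voom. The others kept 1417 without the libraries numbered 1, 1415 without a filter (which adds genes to the adjustment), 1412 without the 2 libraries above, 1404 with library totals and 1375 with only the groups compared. Leaving out single libraries kept 13593 of 14472 values, and 160 called values were lost at least once. Direction reversed for 3 values, all with library totals: Adipoq with cholesterol in scramble cells (0.12, then -0.00672), Hspa5 with siAtf3 in cholesterol (-0.17, then 0.017) and Hspa5 with double silencing in cholesterol (-0.02, then 0.13). The silencing of Atf3 with both siRNAs in control medium (-0.80) was no longer called with any library left out (-0.86 to -0.75).

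Of 198 list calls, 66 held with an estimated correlation. The replicate block in the list test ended 1 call and added 4. The directional test of fry, which does not compare a list with other genes, ended 26 and added 51. Leaving out single libraries ended 72 of 3872 list results and added 91. These 3872 include lists that were not called, which cannot lose a call. Some calls were lost repeatedly, as for immediate early genes in the interaction of siNfe2l1 with cholesterol (6 of 16 fits). The count of genes moved in opposite directions by siNfe2l1 and by siAtf3 added to it fell from 757 to 431.2 in control medium and from 510 to 188.3 in cholesterol when 2 of the 4 siNfe2l1 libraries served each comparison. This both separated the comparisons and left fewer libraries in each (genes called with siNfe2l1 in control medium went from 1663 to 1216), and which of these lowered the count was not tested. The correlation went from -0.27 to -0.0578 and from -0.14 to 0.0110. With the replicate block the cholesterol count was 779, and that of genes moved in the same direction rose more, from 148 to 333.

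The labels do not say what the replicate numbers share, and 0 of 28 pairs of groups had every same-number correlation of deviations over 0.1. Same-number libraries nevertheless correlated slightly more than others (mean r across genes 0.0184 against -0.00601), and 39 of 112 correlated best with their own number. This came mainly from the cholesterol groups, where 23 of 24 same-number correlations were above 0 (mean 0.078 against -0.0255) and library 1 stood highest on the first principal component in each of the 4 groups. This is a hint from the data, not the design, that these numbers share something, and what that is was not tested. With the number as a block siNfe2l1 in cholesterol gave 3694 genes in place of 3382, and of the 17 counts only that of the interaction of siNfe2l1 with cholesterol moved more than 1.5-fold.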

Other observations

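All tests of explanations in this part were decided on after the results they weigh had been seen, so the explanations are hypotheses found and tested on the same data.

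The effect of siAtf3 was measured in separate libraries with and without siNfe2l1. In control medium 1552 genes were higher with siAtf3 in both settings (378.3 by chance) and 1967 lower in both (448.4 by chance), and 15 moved in opposite directions. In cholesterol 2101 were higher in both (613.3 by chance), 2901 lower in both (973.0 by chance) and 46 opposite.

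Genes lower with siAtf3 shared words with the Atf3 mRNA: of 15623 words of 7 bases, GTCAACA had the lowest z in siAtf3 control libraries (-19.2), and in the separate libraries of double silencing against siNfe2l1 it again had the lowest (-18.75), against -0.09 for siNfe2l1 alone. This is consistent with siRNA seed matches in 3′ UTRs such as those of Fads1, Hp, Ctsb and Col3a1. Of the other siAtf3 words, CACCGGA did not pass the limit in cholesterol with double silencing against siNfe2l1 (z = -4.275) or against scramble (z = -3.141). The words do not account for most lower genes in control medium, where they were chosen. There 79.0% of those searched held none. The excess of their share with a word over that of genes not called, divided by 1 minus the latter share, was 14.55%. Of the genes lower over 2-fold 42.75% held one (56 of 131), and 57.78% (26 of 45) with double silencing against siNfe2l1. In cholesterol these 2 shares were lower, at 29.39% (72 of 245) and 40% (34 of 85). Genes for a further ratio were those called lower with double silencing against siNfe2l1 in control medium. Among those without a word, the median effect of siAtf3 was 1.17 times as large in cholesterol, where Atf3 was induced, as in control medium (1648 genes). It was 1.02 times as large among those with a word (442 genes). This choice leaves out genes that respond only in cholesterol, which favours similar effects in both media. Whether the lower genes without a word fell through loss of Atf3 or through another effect of the siRNA cannot be told apart. A single siAtf3 treatment was used throughout, and the ratio lies between the bounds set for either.

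Macrophage markers were higher with siNfe2l1, and while a smaller share of adipocyte RNA would raise the markers of every other cell type, the median of 13 macrophage markers exceeded that of 32 fibroblast, endothelial and smooth muscle markers by 0.6346 in control medium (two-sided permutation test, p = 3e-05 over 100000 permutations), with 4 of the 32 higher. In cholesterol it exceeded them by 0.7406 (two-sided permutation test, p = 2e-05), but 11 of the 32 were higher. These tests weigh a smaller adipocyte share only as the whole cause. As part of the change it was not excluded in either medium. Both tests permuted markers, which are not independent of each other, so their p-values do not measure the spread between libraries. A further list of 20 macrophage genes, of which 18 were tested, had 14 higher and 0 lower (median 0.65), with the protease gene Ctss at 0.78 ± 0.11 and Mpeg1, a pore-forming protein, at 0.66 ± 0.09. This list includes Ms4a7, already named above among the highest genes, so it is not fully independent of these data. Its most abundant gene, Lgals3, which other cells also make, stood at 0.11 ± 0.11 (adjusted p = 0.687) and was the 1 lower gene in cholesterol (-0.32, adjusted p = 0.0429), where 14 were higher. The siNfe2l1 libraries may therefore hold more macrophage RNA, from more such cells or from more transcripts per cell; these were not separated, and no sort of the cells is described in the labels.

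Fibroblast markers were lower with cholesterol and adipocyte genes higher, while macrophage, endothelial and smooth muscle lists were lower only at the preset correlation (adjusted p = 0.271, 0.217 and 0.183 with an estimated correlation), with 1 endothelial and 3 smooth muscle members higher. A scaling of the libraries shifts all genes alike, while the adipocyte and fibroblast medians differed by 1.556. Within the fibroblast, endothelial and smooth muscle lists the members differed by more than a common loss of cells would give if each marker came from 1 cell type alone, which was not tested. The SD among members was 10.7, 17.5 and 11.8 times their median standard error (among endothelial genes Cldn5 rose by 2.68 ± 0.13 and Kdr fell by 2.09). For macrophage markers this ratio was 4.205, under the limit of 5 set for this test, and their standard errors were the largest of the 4 lists, so that loss of the cells and lower transcription in them cannot be told apart there. Fibroblast members all moved down (-2.289 to -0.2204), so loss of the cells was not excluded for that list. A partial loss of any of these cells may also contribute.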
